A study of Homo sapiens with 3 samples.

How the data were processed

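RNA of HaCaT cells transfected with a control siRNA or with 1 of 2 siRNAs against SRSF5 was sequenced in 3 libraries. Per the labels' protocols, siRNA was used at 10 nM with a lipid reagent, RNA was taken with a column kit, and libraries were made with a SMARTer mRNA kit. Per the file headers, the values the authors deposited are FPKM per transcript, with the exons, strand and length of each transcript. The submitters' processing notes name the builds GRCm38, mm10 and GRCh38.p12 without a role. The transcripts carry human Ensembl identifiers, and coordinates are given as the files list them. The aligner and the counting tool are not given in the sources used here.

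The counting behind the values was worked out from the values. Each FPKM times its length was a whole multiple of 1 step in 100% of the values of each library (tolerance 0.05), and the multiples behave as counts of bases, with totals of 4458622346, 4228110936 and 4126967673 base overlaps for the control, siRNA 1 and siRNA 2. In genes with 1 transcript 43.5%, 44.6% and 43.8% of the base counts were multiples of 100, against 0.386%, 0.341% and 0.374% for 99, so 100 bases are called a read equivalent. In 0 of 51524 nested pairs of transcripts did the longer hold fewer bases. A base was therefore counted once for each transcript it overlaps, and isoforms share reads. Of single-exon transcripts inside an exon, 0 of 3172 on the same strand and 49 of 836 on the opposite strand held more bases than the outer one, so strand was used in counting. How reads with several matches were placed is not known, and near-identical genes are uncertain.

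The sum of FPKM over the transcripts of a gene was the gene level, as chosen before the data were examined. Because isoforms share reads this sum is a relative level that grows with the number of listed transcripts, so the text prints the mean per transcript and takes ratios from the sums. Transcripts on alternate scaffolds and duplicate copies (20343 of 247012) were left out. Symbols came from a table of Ensembl identifiers, which matched 60214 of 60506 genes. Ratios are on the scale log2(FPKM + 1), which understates differences of low genes, and genes with a mean FPKM of at least 1 were tested (13923). Mitochondrial transcripts held 13.7%, 14.8% and 10.0% of the base overlaps. Counting errors come from read equivalents of the largest transcript, and intervals cover counting error only, since PCR copies are not independent molecules.

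The main rule took genes at least 2-fold from the control in the same direction in both siRNA libraries, with no p-value. The same count was made with each siRNA library as the odd library. limma 3.58.1 in R 4.3.3 was fitted to log2(FPKM + 1) with a trend, 1 control against 2 siRNA libraries, with Benjamini-Hochberg adjustment. Its spread comes from the difference between the siRNAs (1 residual degree of freedom) and the lone control is assumed to vary like them. When limma was fitted with 1 siRNA library as the odd one, the spread came from the control and the other siRNA library. The odd library was again assumed to vary like those. Where the control stands apart, its difference enters that spread, so few calls in these fits are no check of the main fit. Each library came from a different transfection, but nothing says that any transfection was repeated in separate cultures. The p-values therefore measure only the spread between these samples, which holds differences between the siRNAs and may in part be technical. No counts per gene were held, so no count model was run. Simulated data were made from the gene means with the spread between the siRNAs, in 100 draws without changes and 1 with 200 changed genes. Over 13923 genes, for the control against both siRNAs, the rule recovered 38%, 70%, 92% and 100% of genes planted at a log2 size of 1, 1.5, 2 and 3, and limma 0%, 4%, 22% and 84%. Among unchanged genes the rule took 276 and limma 0.

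Written before the data were examined were 30 gene lists. For each the median ratio per siRNA was set against 10000 random lists matched on expression in 20 bins. Random lists hold unrelated genes, so a list whose genes move together reaches extreme percentiles more easily. Percentiles describe these libraries and are not p-values, and those of both siRNAs share the 1 control library. Members at least 1.5-fold away in both were counted, and limma was read over all genes and adjusted over the list alone. The adjustment over a list alone was made within that list and does not cover the number of lists, 30. Isoform shares are the FPKM of a transcript over the sum of its gene, in genes of at least 5 FPKM in every library. A shift of at least 20 points in both was the rule, and limma on the arcsine square root was the test. In simulated shares 100% of 200 planted shifts of 30 points were recovered, which a rule of 20 points makes nearly certain in advance. The shifts were added to the shares themselves. Recovery of true isoform changes, which move these shares less, was not tested. Regions were taken from nested pairs whose difference is a single block, with at least 20 read equivalents in 1 library and a coverage of at least 5 on the shorter transcript.

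The genes named were SRSF5, the 12 higher and 12 lower in both with the largest smaller ratio (at least 5 FPKM in 1 library), up to 4 members of each list by the same measure, any SR protein gene, 10 transcripts for shares and 5 genes in each direction between the siRNAs. Not every result that this rule takes is reported here. Members named because limma called them over the list alone, and SCGB1A1, FOXA1, KRT5, IFITM1, PTPRC, TMEM63C, UNC50 and the mitochondrial ribosomal RNAs were chosen after their values were seen. Other pseudocounts, filters, scalings, gene summaries and fold sizes were tried, and a mean over transcripts, alternate scaffolds, rescaling without mitochondrial transcripts, a minimum of 100 read equivalents and a correction for GC content and length were added after the data were seen. Python 3.11.15 with numpy 2.4.6, pandas 2.3.3, scipy 1.17.1 and matplotlib 3.10.9 was used.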

Results

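The series asked how gene expression in HaCaT cells depends on SRSF5. HaCaT is an immortalized human keratinocyte line, and SRSF5 is a serine and arginine rich protein that binds RNA and takes part in splice site choice. Cells were transfected with 10 nM of a control siRNA or of 1 of 2 siRNAs against SRSF5, called siRNA 1 and siRNA 2 here. There were 3 libraries, 1 for each transfection, so the control had no replicate and the SRSF5 siRNA group held n = 2 with a different siRNA in each. Each library listed 247012 transcripts with an FPKM value. The largest transcripts of all genes together held 18323681 equivalents of a 100-base read in the control, 17708195 with siRNA 1 and 15864985 with siRNA 2. Levels below are the mean FPKM over the listed transcripts of a gene. Log2 ratios are of the summed FPKM plus 1, siRNA library over control, and where a pair of ratios is given the first is siRNA 1 and the second siRNA 2.

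The targeted gene was lower with both siRNAs. SRSF5 (ENSG00000100650.15, chromosome 14, 69726900 to 69772005, plus strand, GRCh38) had a level of 4.95 in the control, 2.33 with siRNA 1 and 0.983 with siRNA 2. These levels were 47.1% and 19.8% of the control, or a log2 ratio of -1.67 ± 0.85 (SD, n = 2) that was -1.07 for siRNA 1 and -2.27 for siRNA 2. The largest SRSF5 transcript held 363, 195 and 84.3 read equivalents in the 3 libraries, which gave counting errors of 0.13 and 0.17 on the log2 ratios. All 19 listed SRSF5 transcripts were lower, at 42.1% to 56.7% of the control with siRNA 1 and 15.9% to 28.1% with siRNA 2. A base was counted for each transcript it overlaps, so these 19 values share reads and are not separate evidence. In limma, where the spread comes from the difference between the siRNAs, SRSF5 did not pass (log2 -1.67, SE 0.48, Benjamini-Hochberg adjusted p = 1.00).

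**Figure D1:**
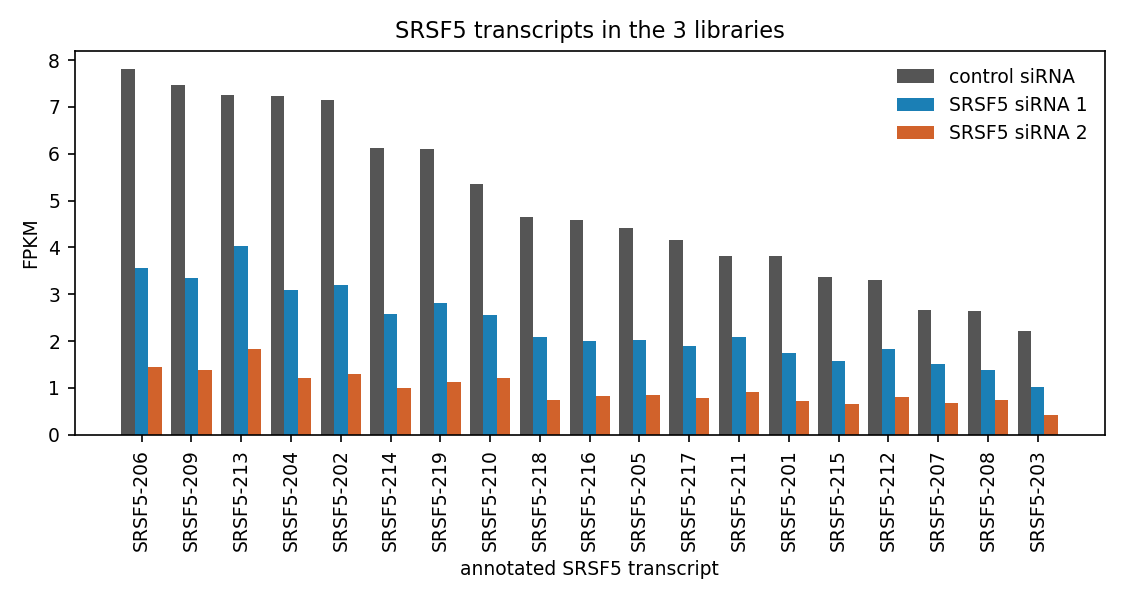
FPKM (vertical axis, linear from 0) of each of the 19 annotated SRSF5 transcripts (horizontal axis) in the control siRNA, SRSF5 siRNA 1 and SRSF5 siRNA 2 libraries, 1 bar per library with no error bar. Each transcript was highest in the control and lowest with siRNA 2. The transcripts share reads, so the bars are not independent.

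The other SR protein genes stayed near the control. The 12 measured genes of this family had a median log2 ratio of -0.04 and -0.02, and 0 of them were at least 1.5-fold away in both siRNA libraries. SRSF4 had the widest range apart from SRSF5, with levels of 14.1 in the control, 11.3 with siRNA 1 and 22.1 with siRNA 2. SRSF9 was at 15.4, 13.3 and 12.3, TRA2A at 4.39, 4.80 and 5.98, and SRSF7 at 6.18, 6.15 and 6.02. SRSF12 was listed at 0 in the 3 libraries. Among 33 other splicing regulators the median was -0.05 and 0.03, with 1 gene at least 1.5-fold lower in both, the muscleblind family gene MBNL2 (-1.03 and -0.80). The splicing kinases (8 measured, 0 apart in both) had medians of -0.01 and 0.17, and the nonsense-mediated decay factors (14 measured, 0 apart) had medians of -0.12 and 0.05.

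The first comparison set the control against both siRNAs. The genes farthest above the control in both were OLR1, a scavenger receptor for oxidized lipoprotein (chromosome 12, 10158301 to 10172138), at 0.522, 3.95 and 4.39 (log2 ratios 2.72 and 2.87), and SERPINB7, a serine protease inhibitor of the epidermis (chromosome 18, 63752935 to 63805376), at 1.5, 10.4 and 11.4 (2.67 and 2.80). The alkaline phosphatases ALPG (2.48 and 2.85) and ALPP (2.99 and 2.33) followed, although these neighbouring genes are near-identical copies whose reads can be shared. ANKRD1 (2.45 and 2.18), CCN1 (5.16, 21.5 and 21.1), the integrin-like ITGBL1 (1.87 and 2.04), SYT14 (1.98 and 1.82), the collagen hydroxylase P3H2 (1.75 and 1.83), the collagenase MMP13 (1.68 and 2.05) and MYADM (1.67 and 1.84) completed the higher genes, with PSG5 (2.64 and 1.82), a member of a multigene family at 5.24 read equivalents in the control.

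Below the control in both was IFI6, an interferon-induced gene (chromosome 1, 27666064 to 27672198), at 14.1, 2.32 and 1.56 (-2.44 and -2.93). IFI27, another such gene, was at 0.693, 0.123 and 0.146 (-2.00 and -1.84). The largest IFI27 transcript held only 25.7, 7.40 and 12.4 read equivalents, which gave counting errors of 0.60 and 0.50 on its ratios. The polymeric immunoglobulin receptor PIGR was at 4.48, 1.08 and 0.785 (-1.76 and -2.11), and LCN2, an iron-binding antimicrobial protein, at 23.6, 7.97 and 5.82 (-1.55 and -1.99). The acetyl-CoA synthetase ACSS2 had ratios of -1.41 and -1.58, and GMFB of -1.38 and -1.95. The antiviral genes OAS2 (-1.99 and -1.37) and BST2 (-1.30 and -1.75), the semaphorin receptor NRP2 (-1.31 and -1.59), the lipid transporter MFSD2A (-1.28 and -1.43), the splicing regulator MBNL3 (-1.97 and -1.26) and the noncoding RNA LINC00342 (-1.25 and -1.51) were the remaining lower genes.

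Of 13923 genes tested, 102 were at least 2-fold higher and 39 at least 2-fold lower in both siRNA libraries, 141 in all. When each SRSF5 siRNA library in turn was set against the other two, 140 genes passed for siRNA 1 and 482 for siRNA 2. Simulated unchanged libraries with the spread seen between the siRNAs, which includes any real difference between them, gave a mean of 271 such genes (228 to 308 in 100 draws). With the mean over transcripts in place of the sum 57 genes passed, with the highest transcript of each gene 71, and with a pseudocount of 0.1 FPKM 297. Without siRNA 2 the count was 421 and without siRNA 1 it was 1021. In limma 0 genes had a Benjamini-Hochberg adjusted p below 0.05, the smallest being 0.10 for OLR1 and SERPINB7. At an unadjusted p below 0.05 limma gave 416 genes, where 696 are due by chance, and a robust fit called 3 genes, ALPP, SERPINB7 and OLR1.

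**Figure D2:**
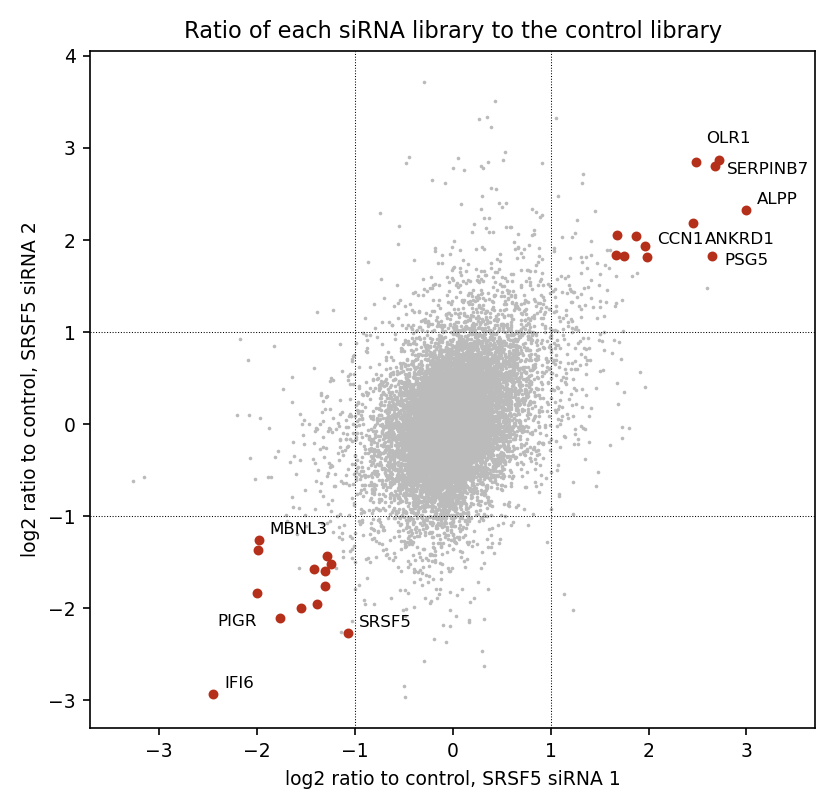
Log2 ratio to the control library for siRNA 1 (horizontal axis) and siRNA 2 (vertical axis), 1 grey point per tested gene. Red points are SRSF5 and the 12 genes highest and 12 lowest in both, and dotted lines mark 2-fold, beyond which 102 genes lay at the upper right and 39 at the lower left.

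Interferon-induced genes stood below the control with both siRNAs. The 30 measured members had a median log2 ratio of -0.46 and -0.61, below each of 10000 random lists matched on expression (percentile 0 for each siRNA). Such percentiles are easily extreme for genes that move together, since random lists hold unrelated genes. Ribosomal protein genes, for example, lay at percentiles 0.17 and 99.76. Both percentiles also share the 1 control library, so they are not independent. With both siRNAs 9 members were at least 1.5-fold lower and 0 higher. Adjusted over the list alone, limma called 6 members, all lower: IFI6 (adjusted p = 0.0017), IFI27 (0.011), OAS2 (0.030), BST2 (0.034), and MX1 and XAF1 (0.037 each). Over all genes limma called 0 of them. With siRNA 1 as the odd library 4 members were at least 1.5-fold apart and with siRNA 2 6. Limma with an siRNA library as the odd one is no check here, since the control's own difference enters its spread. With median scaling or the mean over transcripts, limma of the control against both siRNAs called fewer members over the list alone. SCGB1A1 (-1.13 and -1.18) and FOXA1 (-0.93 and -1.04), picked after their values were seen, were also lower in both siRNA libraries, beside PIGR and LCN2 above. No list of secretory epithelium genes was written, so these genes do not speak for such a class.

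Target genes of YAP, a transcriptional coactivator that responds to cell contact and tension, stood above the control. Their median was 0.88 and 0.54 over 18 measured members (percentile 100 for each siRNA), with 7 at least 1.5-fold higher in both and 0 lower. Adjusted over the list alone, limma called 5 members, all higher: ANKRD1 (adjusted p = 0.0027), CCN1 (0.0030), AJUBA and CCN2 (0.020 each) and GADD45B (0.024). CCN2, a matricellular protein, was at 0.556, 2.69 and 5.58, and AJUBA, a LIM-domain protein, at 3.48, 8.23 and 9.71. Over all genes limma called 0 of these. With siRNA 1 as the odd library 4 members were at least 1.5-fold apart and with siRNA 2 2. Limma in those fits is again no check, since the control's own difference enters its spread.

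**Figure D3:**
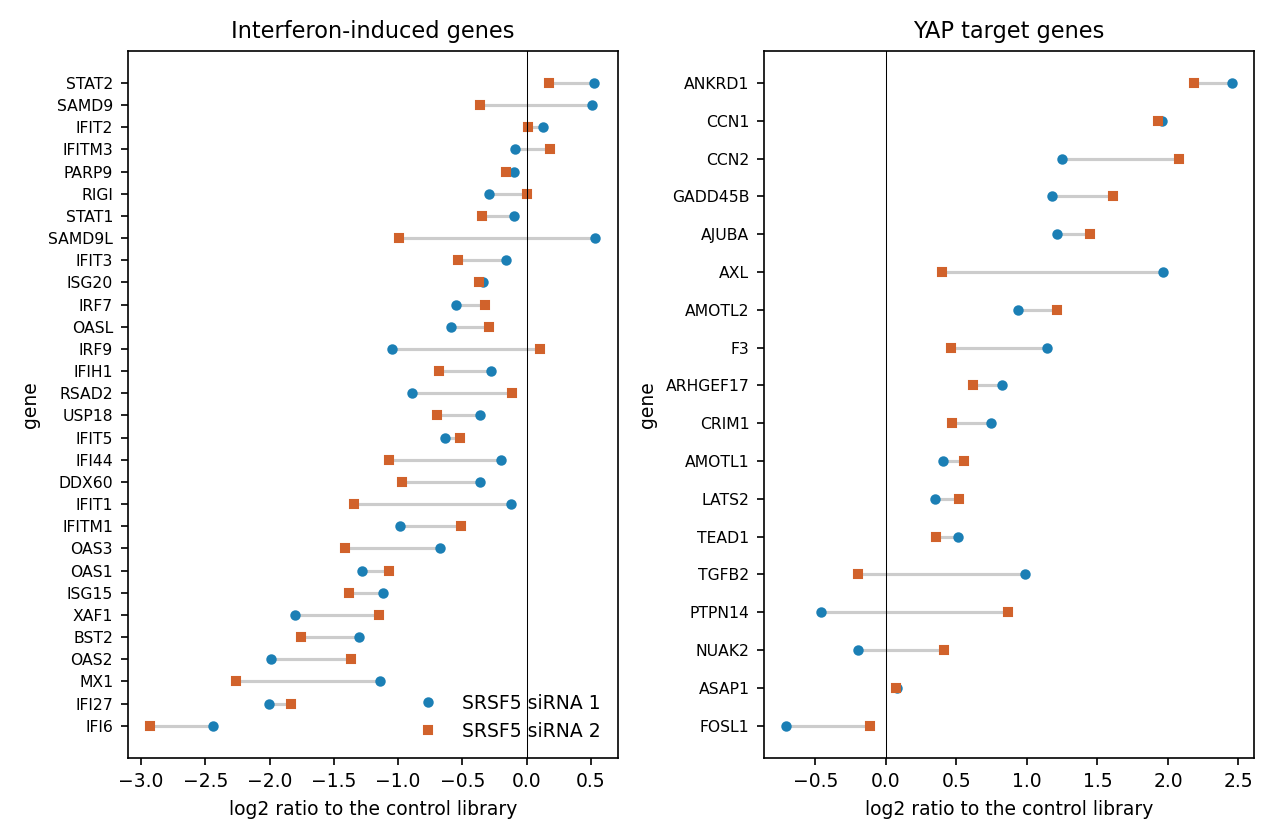
Log2 ratio to the control library (horizontal axis) of each measured interferon-induced gene (left, 30 genes) and YAP target gene (right, 18 genes), with siRNA 1 as circles and siRNA 2 as squares. The list medians were -0.46 and -0.61 on the left and 0.88 and 0.54 on the right.

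Genes of sterol synthesis and uptake were lower, and further so with siRNA 2. Their median was -0.35 and -0.96 over 24 measured members (percentile 0 for each siRNA), with 5 at least 1.5-fold lower in both and 0 higher. Among them were MVD (-0.83 and -1.12), MSMO1 (-0.68 and -1.43) and ACAT2 (-0.90 and -0.66). In limma 0 of the 24 passed, over all genes or adjusted over the list alone (smallest adjusted p = 0.18). With siRNA 2 as the odd library 11 members were at least 1.5-fold apart and 6 passed over the list alone, and with siRNA 1 as the odd library 0 and 0.

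Matrix and mesenchymal genes had a median of 0.57 and 0.67 over 19 members (percentile 100 for each siRNA), with 7 at least 1.5-fold higher in both and 0 lower. MMP10 (1.08 and 2.48), SPARC (0.99 and 1.51), TGFBI (1.14 and 0.92) and MMP1 (0.83 and 2.06) led them. In limma 0 passed over the list alone (smallest adjusted p = 0.078), and with siRNA 2 as the odd library 6 did. By the 1.5-fold rule 2 members were apart with siRNA 1 as the odd library and 6 with siRNA 2. COL1A1, the single fibroblast marker of 9 above the filter, was at 0.193, 0.386 and 0.376. Basal keratinocyte genes had a median of 0.27 and 0.49 over 16 members (percentiles 99.99 and 99.98). With both siRNAs 9 members were higher and 4 lower, so the list did not move as a whole. At least 1.5-fold apart in both were 3, CAV1 (0.82 and 1.00), LAMA3 (0.74 and 0.88) and LAMB3 (0.64 and 0.76). Limma called none of the basal genes over the list alone. The 22 junction genes had a median of 0.01 and 0.18. Among them CDH1, which encodes E-cadherin, was at 6.0, 22.3 and 18.9, and CLDN1 had ratios of 1.10 and 1.12. Limma called CDH1 over the list alone but not over all genes. Nuclear genes of oxidative phosphorylation had a median of -0.23 and -0.31 over 33 members (percentiles 0.15 and 0.04), with 0 at least 1.5-fold lower in both. With siRNA 2 as the odd library 6 were apart and with siRNA 1 0, and of the basal genes 3 and 1.

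**Figure D4:**
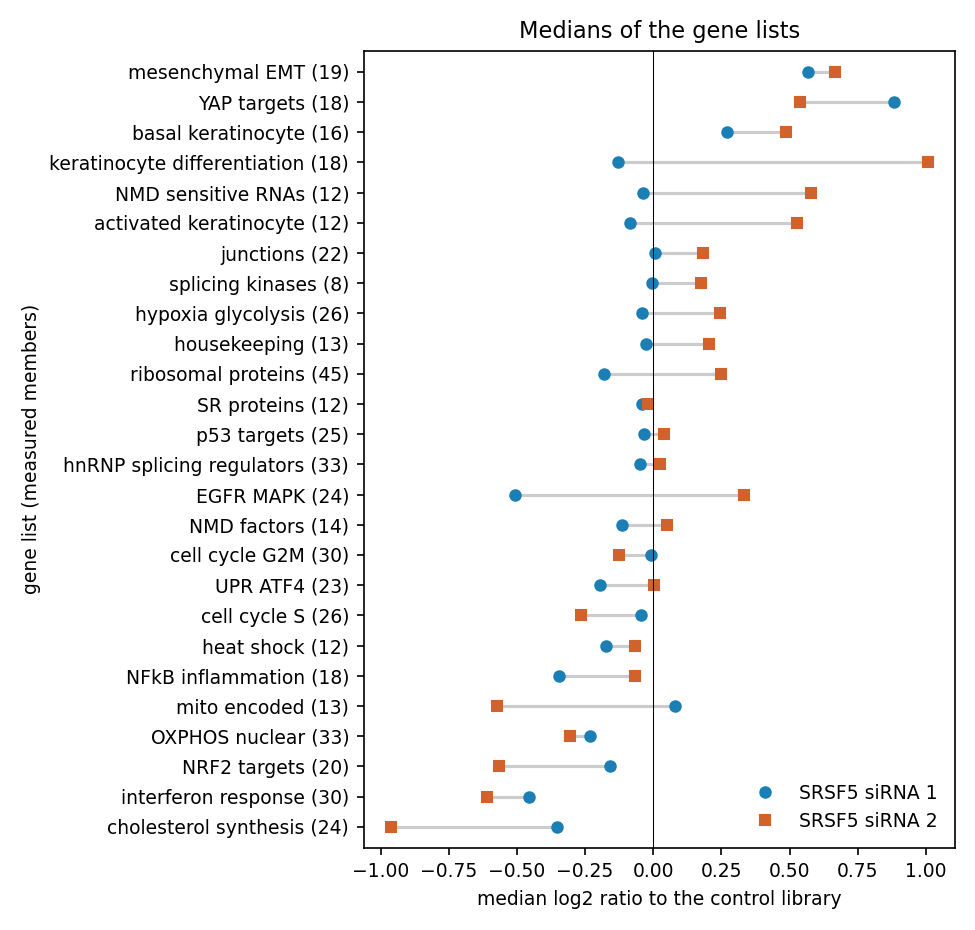
Median log2 ratio to the control library (horizontal axis) of each gene list with at least 5 measured members (vertical axis, number of members in parentheses), with siRNA 1 as circles and siRNA 2 as squares. Medians of mesenchymal, YAP target and basal keratinocyte genes lay above 0 and those of sterol, interferon and nuclear oxidative phosphorylation genes below 0 for both siRNAs.

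The next comparison asked how alike the siRNAs were. Across genes, which are not independent replicates, the log2 ratios had a Pearson correlation of 0.372 and a Spearman correlation of 0.326. Unchanged groups sharing 1 control library were simulated with an equal spread in each library, which by itself sets the correlation at 0.50. The measured ratios had unequal SDs, 0.405 with siRNA 1 and 0.558 with siRNA 2, so 0.50 is no reference fitted to these data. The covariance was 0.0841, against 0.153 in the simulation (difference -0.0693), and 59.5% of genes had ratios of the same sign against 66.5%. Of the genes at least 2-fold higher, 236 with siRNA 1 and 627 with siRNA 2, 102 were shared where independent lists would share 10.6. Of the lower genes, 185 and 394, 39 were shared against 5.24. Independent lists leave out the shared control, which could not be split. The simulated covariance holds the spread between the siRNAs, real differences included, and so may lie too high as a reference. The simulated 66.5% of the same sign, like the correlation, follows from the equal spread.

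The siRNA libraries differed from each other in many genes. Between them 552 genes were at least 2-fold higher and 401 at least 2-fold lower with siRNA 2, 953 in all, or 425 with the mean over transcripts and 1469 with a pseudocount of 0.1 FPKM. Far higher with siRNA 2 were the suprabasal keratin KRT1, at 0.807, 0.456 and 9.25 in the control, siRNA 1 and siRNA 2 libraries, the noncoding gene ENSG00000286966 at 1.72, 1.22 and 34.9, CALB1 at 0.098, 0.045 and 1.26, C12orf75 at 10.0, 2.12 and 19.1, and the metallothionein MT1H, 1 of a family of close copies, at 1.18, 1.77 and 18.7. Far lower with siRNA 2 were ADAM9, a membrane protease, at 16.5, 20.4 and 2.91, the heme synthesis enzyme FECH at 3.47, 4.37 and 0.493, HFE at 1.69, 1.19 and 0.154, APOL1 at 1.05, 2.40 and 0.232, and FBXW10B at 0.855, 2.17 and 0.117. Each siRNA had 1 library, so these differences have no replicate check.

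Several gene groups separated the siRNAs. Keratinocyte differentiation genes, 18 measured of 39 listed, had a median of -0.13 with siRNA 1 and 1.01 with siRNA 2. The median difference of 0.98 lay at percentile 100 of random lists. With both siRNAs 5 members were higher and 4 lower, GRHL1 (-0.39 and -1.71) among the lower ones. FLG, the precursor of a cornified envelope protein, was at 0.179, 0.703 and 8.16. KLK5 (1.67 and 1.32) was the member limma called over the list alone, but not over all genes. Activated keratinocyte genes had medians of -0.08 and 0.53 over 12 members, with KRT17 (1.45 and 2.31) higher and LCN2 lower in both. Limma called KRT17 and LCN2 over the list alone but not over all genes. Genes listed for EGF receptor and MAPK signalling had medians of -0.51 and 0.33 over 24 members, and ribosomal protein genes -0.18 and 0.25 over 45. The 13 mitochondrially encoded mRNAs had medians of 0.08 and -0.57. NRF2 target genes had medians of -0.16 and -0.57 over 20 members, with AKR1B10 at 18.0, 12.9 and 4.27. In limma 0 members of these last 4 lists passed over the list alone. With siRNA 2 as the odd library 12 of the mitochondrial mRNAs passed, 10 differentiation genes, 6 NRF2 targets, 6 junction genes, 4 activated keratinocyte genes, 3 basal genes, and 0 of the EGF receptor and ribosomal protein lists. Of the EGF receptor list 10 members were at least 1.5-fold apart with siRNA 1 as the odd library and 5 with siRNA 2, and its medians lay at percentiles 0 and 99.49.

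Isoform shares were compared because SRSF5 acts in splicing. Among 88974 transcripts of 8313 genes, 1 moved by at least 20 percentage points the same way in both siRNA libraries. This was IFITM2-201 (chromosome 11, 308408 to 315272), whose share of IFITM2 was 54.8%, 29.3% and 30.8%. Of its 382 bases 351 lie inside exons of IFITM1, an interferon-induced gene with ratios of -0.99 and -0.51, so its value also holds reads of that gene. With either siRNA library set against the other two, 0 transcripts passed for siRNA 1 and 1 for siRNA 2. The next transcripts moved less. PCGF5-202 was at 54.3%, 41.4% and 44.7%, DLEU2-209 at 12%, 21.4% and 20.9%, PCSK5-204 at 27.3%, 17.9% and 18.7%, and MAP3K13-212 at 38.1%, 47.9% and 46.1%. Some of these rest on few reads. DLEU2-209 held 21.4, 31.6 and 26.2 read equivalents and PCSK5-204 65.8, 27.5 and 36.5, so counting error on their shares is large. In the methyltransferase gene SETD7 (chromosome 4, minus strand), SETD7-201 was at 19.1%, 27% and 28.3% and SETD7-207 at 10.3%, 1.74% and 1.11%. In limma on the arcsine square root of the shares 0 transcripts passed a Benjamini-Hochberg adjusted p of 0.05, and 3263 had an unadjusted p below 0.05, where 4449 are due by chance.

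A base was counted for each transcript it overlapped, so shares change less than isoforms do. Pairs of transcripts with 1 nested inside the other gave 968 regions, of which 39 passed the depth filter. They were 21 cassette exons, 11 retained introns and 7 alternative splice sites, several of them overlapping in IGFL2-AS1. Of these 39, 0 were at least 1.5-fold apart in relative coverage in both siRNA libraries. The filter asked for 20 read equivalents in only 1 library, and the ADAM9 region held 6 with siRNA 2. Changes in shallow regions could be missed, so the count of 0 does not show that splicing was unchanged. With siRNA 1 and siRNA 2 as the odd library the counts were 2 and 4. A cassette exon of SRSF6 (chromosome 20, 43460703 to 43460852) had a relative coverage of 3.24, 3.49 and 3.45 from 334, 390 and 296 read equivalents.

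The listed markers of melanocytes, fibroblasts and endothelial cells were low. The highest level of any of the 7 melanocyte markers was 0.210 in the control, 0.407 with siRNA 1 and 0.291 with siRNA 2, and of the 9 fibroblast markers 0.193, 0.386 and 0.376. Of the 6 endothelial markers the highest were 0.343, 0.130 and 0.138, with CDH5, the only member measured, at ratios of -1.27 and -0.86. In limma it passed adjusted over the list alone (adjusted p = 0.022), which for 1 gene is no adjustment, and over all genes its Benjamini-Hochberg adjusted p was 1.00. Of the 9 immune markers CD68, a lysosomal protein also made outside macrophages, was at 7.22, 4.89 and 4.47, and PTPRC was at 0.0077, 0.017 and 0.0069. Outside these lists SCGB1A1, which encodes a secreted protein of airway club cells, was at 1240, 567 and 546, and FOXA1, a transcription factor of secretory epithelia, at 20.5, 10.7 and 9.89.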

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

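Alternatives were chosen before the data were examined, except the mean over transcripts, alternate scaffolds, rescaling without mitochondrial transcripts, the read minimum and the GC and length correction. The 141 genes at least 2-fold from the control in both libraries became 297 with a pseudocount of 0.1 FPKM, 52 with 5 FPKM, 71 with the highest transcript, 57 with the mean over transcripts, 649 at 1.5-fold and 20 at 3-fold. A larger pseudocount and the smaller values of single transcripts shrink ratios by construction. Counts were 98 to 163 under the other filters, scalings and added alternatives. With a single siRNA they ran from 421 to 1021. The limma count of 0 became 3 with a robust fit and 5 with the highest transcript (IFI6, ANKRD1, ALPG, SERPINB7 and OLR1), and stayed 0 under the other settings. The cause was not tested. The correlation of 0.372 was 0.359 at a mean of at least 5 FPKM and 0.389 with a pseudocount of 0.1 FPKM. The 953 genes apart between the siRNAs were 1469 with a pseudocount of 0.1 FPKM and 425 with the mean over transcripts. The 6 interferon genes called over the list alone were 3 with median scaling and 2 with the mean over transcripts. The isoform count of 1 was 2 in genes of at least 2 FPKM, where TMEM63C-207 joined, 0 at 30 points, and 1 to 3 with a single siRNA. The log2 ratio of SRSF5 stayed negative throughout, from -2.27 to -1.07 with a single siRNA. All 48 values of named genes and 12 of leading lists under another pseudocount or median scaling kept their direction, but 12 and 2 of them moved by more than the spread between the siRNAs. With a pseudocount of 0.1 FPKM ANKRD1 went from 2.32 to 3.59 and PSG5 from 2.23 to 3.20. DESeq2 on counts was not run because no counts were held. No paired analysis was possible because the groups share fewer than 2 replicate numbers. Depth limits low genes most, since PSG5 and IFI27 held 5.24 and 7.40 read equivalents in their lowest libraries.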

Other observations

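SCGB1A1, which encodes a secreted protein of airway club cells, was among the abundant RNAs of these libraries, with a mean FPKM per transcript of 1240 in the control, 567 with siRNA 1 and 546 with siRNA 2 (log2 ratios -1.13 and -1.18). The keratins KRT5 (205, 233 and 320) and KRT14 (238, 347 and 1055) were also abundant. FOXA1, a transcription factor of secretory epithelia, was at 20.5, 10.7 and 9.89. The identity of the culture was not checked here. These genes were picked after their values were seen, except KRT14.

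The intronic part of SRSF5 was reduced less than its spliced RNA. The bases of the retained intron transcript SRSF5-207 that lie outside the coding transcript SRSF5-217 nested in it are 1544, of which 1500 are in introns between 69768897 and 69770466 on chromosome 14. This part held 85.2, 74.2 and 35.4 read equivalents, or 91.9% of the control with siRNA 1 (95% interval of counting error 67.3 to 125) and 44.8% with siRNA 2 (30.3 to 66.3). SRSF5-217 stood at 45.9% (37.0 to 56.8) and 19.1% (14.1 to 25.8). A retained intron of UNC50 was the region with the widest shared shift of the 39 followed, at log2 ratios of 0.57 and 0.58 from 19.5, 39.5 and 24.5 read equivalents.

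Of the other lists, 3 had a median far from random lists in 1 siRNA library. Targets of nonsense-mediated decay had -0.04 and 0.58 over 12 members (percentile 99.99 for siRNA 2 and 99.77 for the difference between the siRNAs), with GADD45B (1.18 and 1.61) apart in both. S-phase genes had -0.05 and -0.27 over 26 members (percentile 0.72 for siRNA 2 and 0.14 for the difference), with CCNE2 at -0.96 and -1.75. Inflammatory genes of NF-kB had -0.35 and -0.07 over 18 (percentile 0.04 for siRNA 1 and 99.68 for the difference), with CXCL8 at -1.14 and -0.62 and IL6 at 0.29 and 2.81. The remaining lists lay nearer to random lists. Genes of p53 had -0.03 and 0.04 over 25 (percentiles 46.9 and 48.9), with PLK2 (1.38 and 1.49) and GDF15 (-1.41 and -0.92) on opposite sides. Genes of G2 and M phase had -0.01 and -0.13 over 30 (86.6 and 7.35), and genes of the ATF4 response -0.19 and 0.00 over 23 (3.29 and 46.1). Heat shock genes had -0.17 and -0.07 over 12 (8.27 and 18.8), and housekeeping genes -0.03 and 0.20 over 13 (63.2 and 87.1). Hypoxia and glycolysis genes had -0.04 and 0.25 over 26 (53.7 and 98), with the glucose transporter SLC2A1 at -1.03 and -1.45. In limma 0 members of these lists passed over the list alone for the control against both siRNAs. With siRNA 2 as the odd library 6 genes of the ATF4 response did, 3 of hypoxia, 2 of S phase and 2 of NF-kB.

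The explanations in the next paragraphs and what each predicts were chosen after the results were seen, although median scaling itself was a setting planned before.

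The 141 genes apart from the control in both siRNA libraries were weighed first. GC content and length explained 0.283% and 0.667% of the variance of the siRNA 1 and siRNA 2 ratios, and 93.6% of the genes stayed when both were regressed out, which argues against these trends as the whole cause. Variation between single libraries cannot be told apart from a knockdown effect, because 1 control library allows only 3 splits, with 141 genes in the real one and 482 in the highest other, which sets the siRNA 2 library apart. A shared effect of SRSF5 loss stays open.

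The interferon, sterol and YAP target lists were weighed next. After median scaling the smallest of the 6 list medians was still 0.29 away from 0, so these lists moved relative to other genes. The medians of all tested genes were only -0.025 and 0.0455. Median scaling could therefore shift the lists little and is no independent test of scaling. A difference of the control library alone would leave the siRNA libraries alike, and they lay apart by a median of -0.54 for sterol genes (bootstrap SD over genes 0.085, percentile 0 of random lists), -0.18 for interferon genes (SD 0.16, percentile 1.17) and 0.0708 for YAP targets (SD 0.16, percentile 46.51). Effects in proportion to the log2 knockdown of SRSF5 would put the siRNA 1 ratio at 0.470 of the siRNA 2 ratio, and the medians deviated from that by 0.0186 for sterol genes (SD 0.059), 0.39 for YAP targets (SD 0.13) and -0.17 for interferon genes (SD 0.15). A spread over genes holds no variation between libraries, so with 1 library per siRNA neither explanation can be told apart from the other for these 3 lists, and replicate libraries, graded siRNA doses or a rescue of SRSF5 would be needed.

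The 13 mitochondrially encoded mRNAs were lower with siRNA 2, at a median log2 ratio of -0.57 (SD over genes 0.13, range -0.88 to -0.42). Scaling of the siRNA 2 library would lower other genes alike, and the median of all tested genes was 0.0455, so these mRNAs were lower relative to other genes. FPKM is already scaled to the total of each library, so that median is no independent test of scaling. Proportion to the knockdown would put siRNA 1 at -0.27 and its median was 0.0795 (SD over genes 0.078), but with 1 library per siRNA a dose relation cannot be told apart from variation between libraries. The ribosomal RNAs MT-RNR2 (-0.0886) and MT-RNR1 (-0.35) were both nearer to the control than any of the mRNAs, which goes against a lower yield of all mitochondrial RNA alike, but so few members of the class exclude nothing and it cannot be told apart. An effect of siRNA 2 that does not pass through SRSF5 was not tested.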
